A study of Mus musculus with 6 samples.

How the data were processed

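Interscapular brown adipose tissue of C57BL/6N mice was profiled by paired-end sequencing of total RNA, with libraries made with the NEBNext Ultra II kit and run on a NovaSeq6000, per the labels. There were 6 libraries in 2 groups of 3, wild type and ADCY3∆AT, a knockout of the AT form of adenylyl cyclase 3. The series design text calls the depot inguinal, while every sample label calls it interscapular, and the sample labels are followed here. Replicates carry numbers but the labels do not say that each is a separate animal, so the p-values measure the spread between these samples, which may be partly technical.

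The deposited table holds estimated counts per Ensembl gene, not normalised, and 31.6% of its values are not whole numbers. Salmon, StringTie, edgeR and the mouse build GRCm38 are named in the submitters' processing notes, without versions or roles. Settings of the quantification are not given in the sources used here. A quantifier that divides reads among overlapping or near-identical transcripts can list a row at exactly 0 while a related row takes its reads. The table has 54385 rows, of which 54131 matched a gene symbol in GENCODE M21 (GRCm38) and 254 did not. Rows without a symbol held a median of 0.0271% of a library. Column headers were matched to the sample labels, and no value column was left unmapped.

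Estimated counts were rounded to whole numbers. Genes were kept with filterByExpr on the genotype groups, which left 18114, and libraries were scaled with TMM factors. The test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) with genotype as the only term, Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are ADCY3∆AT relative to wild type, and the standard error given with each is the one implied by the F statistic. CPM values are TMM-normalised. Log2 CPM values used a prior count of 2. Gene lists were tested with camera in limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01 and adjustment over the 31 of 33 lists with at least 5 tested members. The lists were also tested with a correlation estimated per list and with fry, for change in one direction and in either direction. For each list, members were counted past the threshold over all genes and adjusted over the list alone. For Adcy3 an exact two-sided permutation test of log2 CPM was added, with 20 assignments and a smallest possible p of 0.1. For the row not in the annotation, listed at 0 in ADCY3∆AT, the floor was taken as 3 counts per library, which covers counting error only. Other rows holding a 0 keep the fold change of the edgeR fit.

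The groups, tests, gene lists, alternatives and the rule for naming genes were chosen before the data were examined. The rule names Adcy3. It then names, in each direction, the 12 largest changes among genes past the threshold whose groups do not overlap, with a mean log2 CPM of at least 1 and a proper gene symbol. Where fewer than 5 genes qualified, the 5 lowest p-values of that direction under the same limits are named and said not to pass. For each list described, the 3 tested members with the lowest p-values are named, with Ucp1, Ppargc1a, Dio2, Cidea and Elovl3 added for the thermogenic list, and genes flagged by rule would be added. A gene that the rule names is not reported here. The row not in the annotation, Acta1, Ckm, Trpc2, Xntrpc and the genes beside Adcy3 were singled out after their values had been seen.

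The alternatives were RLE factors, library totals alone, DESeq2 1.42.0, limma voom with and without quality weights, edgeR with robust estimation, no low-count filter, a filter of at least 1 CPM in at least 3 libraries, removal of mitochondrially encoded genes, an adjusted p of 0.1, leaving out each library, the replicate number as a block, and 1 surrogate variable from sva 3.50.0.

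Library totals ranged from 44826777 to 54933588 estimated counts. No pair of libraries agreed within sampling noise, since the chi-square per degree of freedom ranged from 24.4 to 72.6 over pairs, so none was treated as a duplicate. The tests were tried on simulated data for the ADCY3∆AT against wild type comparison, with negative binomial counts for 18114 genes drawn at the real means, library sizes and dispersions and 200 genes changed. There edgeR recovered 29.9% of genes changed by 1.5-fold, 59.7% of those changed by 2-fold and 89.4% of those changed by 4-fold, and 10.5% of its calls were genes not changed. DESeq2 recovered 49.3%, 67.2% and 87.9%, and 24.4% of its calls were genes not changed. Each gene was drawn independently, without shifts shared between genes of a library, so these shares need not hold for the real libraries.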

Results

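RNA abundance was measured in interscapular brown adipose tissue, the heat-producing fat between the shoulder blades, of C57BL/6N mice aged 20 weeks. The mice had been fed chow to 8 weeks of age and a high-fat diet for 12 weeks, and were kept at 4 °C for 24 h. There were 3 wild-type libraries and 3 libraries of ADCY3∆AT mice, which lack the AT form of adenylyl cyclase 3, an enzyme that makes cyclic AMP. Library totals were 54933588, 45671895 and 44826777 estimated counts in wild type and 46532326, 48502809 and 45676498 in ADCY3∆AT. The comparison asks how brown fat of cold-exposed mice differs when this truncated, cold-induced form is missing.

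The targeted gene was examined first. Adcy3 (ENSMUSG00000020654, a protein-coding gene on the plus strand of chromosome 12, 4133103 to 4213525, GRCm38) had 676.9, 727.8 and 651.9 CPM in the wild-type libraries and 348.5, 341.9 and 505.6 CPM in the ADCY3∆AT libraries. The means were 686 ± 38.7 CPM and 399 ± 92.7 CPM (SD, n = 3 each), and every ADCY3∆AT library lay below every wild-type library. The log2 fold change was -0.78 ± 0.14 (SE), which did not pass in edgeR (adjusted p = 0.158) and passed in DESeq2 (adjusted p = 4.26e-07). The exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. Without ADCY3∆AT replicate 3 the fold change was -0.99 and passed in edgeR (adjusted p = 0.00338), and it also passed with no low-count filter (adjusted p = 0.00321).

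A row that is not in the GENCODE M21 annotation, ENSMUSG66666620654, shares the last digits of its identifier with Adcy3. The files do not name it, and it was singled out after its values had been seen. It had 552.7 ± 75.6 CPM in wild type (SD, n = 3) and was listed at 0 in all 3 ADCY3∆AT libraries. Against a floor of 3 counts per library, it was at least 8676-fold lower in ADCY3∆AT. Whether the same reference index served both genotypes is not given in the sources used here, and a row missing from the index used for ADCY3∆AT would also be listed at 0, so the fold and the call hold only if it was the same. The difference passed in edgeR (adjusted p = 7.9e-06) and in DESeq2 (adjusted p = 3.54e-43). In wild type the row held 44.5 ± 3.2% (SD, n = 3) of the summed CPM of both rows. That sum was 3.11-fold higher in wild type than in ADCY3∆AT. How reads were divided between both rows is not given, so the lower value of the Adcy3 row alone may partly reflect that division.

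**Figure D1:**
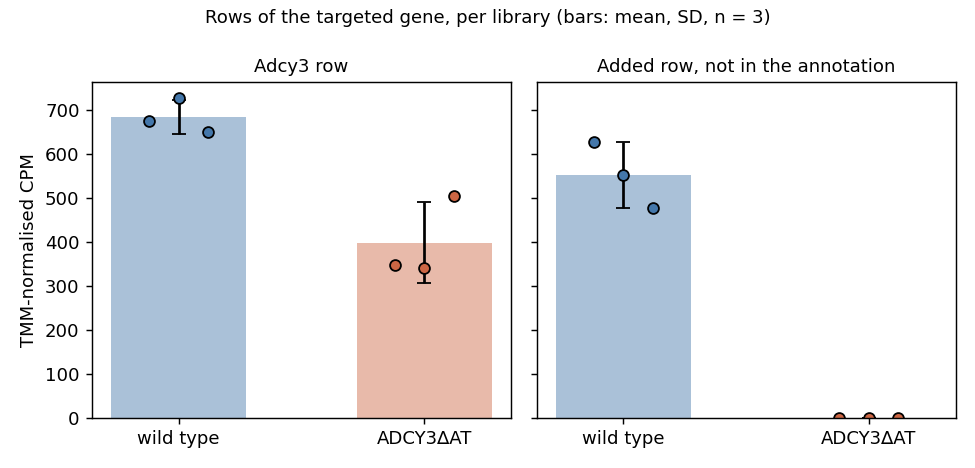
TMM-normalised CPM (y axis, from 0) of the Adcy3 row and of the added row in wild type and ADCY3∆AT, with points for libraries and bars for the mean and SD of 3 libraries. The added row lies between 477.4 and 628.6 CPM in wild type and is listed at 0 in all 3 ADCY3∆AT libraries, while the Adcy3 row keeps a mean of 399 CPM there.

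Over all 18114 genes tested, that row was the only call of edgeR, with 0 genes higher and 1 lower in ADCY3∆AT. At an unadjusted p under 0.05 there were 1995 genes (11%), 948 higher and 1047 lower. DESeq2, run without that low-count filter and with 19977 genes tested, called 229 genes, 88 higher and 141 lower. On the 18114 genes limma voom called 2, and edgeR without a low-count filter called 214 of 30714. The groups did not overlap for 2992 genes (16.5%). Chance gives 10% on average over the possible splits of the libraries. The share in each other split was not computed, so an excess over chance is not established. Leaving out ADCY3∆AT replicate 3 raised the edgeR count to 66, and leaving out wild-type replicates 1, 2 and 3 gave 2, 4 and 2.

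No further gene passed in edgeR, and the lowest p-values of each direction are given as values. Higher in ADCY3∆AT were Tmem140 (log2 fold change 0.55 ± 0.07, SE), the basement membrane collagen Col15a1 (0.49 ± 0.07), the stress-induced chromatin protein Nupr1 (0.58 ± 0.08), Fam49a (0.48 ± 0.07) and the protein kinase Prkd2 (0.46 ± 0.07), each with an edgeR adjusted p of 0.141. Tmem140 had 56.7 ± 3.5 CPM in wild type and 83.1 ± 6.6 CPM in ADCY3∆AT (SD, n = 3 each). Lower were the sodium channel subunit Scn4b (-0.50 ± 0.05, edgeR adjusted p = 0.116), Ldb3 of the muscle Z-disc (-2.26 ± 0.33) and Klhl41 of muscle (-2.31 ± 0.34). Gpcpd1 (-0.55 ± 0.08) and Tmem38a, a cation channel of the sarcoplasmic reticulum (-1.51 ± 0.23), were also lower. The edgeR adjusted p was 0.141 for Ldb3, Klhl41, Gpcpd1 and Tmem38a. Scn4b had 39.6 ± 1.1 CPM in wild type and 28.0 ± 1.2 CPM in ADCY3∆AT (SD, n = 3 each). All 10 genes passed in DESeq2, with adjusted p-values from 8.48e-12 (Ldb3) to 0.0016 (Prkd2).

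The libraries were set beside each other by principal components of log2 CPM. The first component held 38.2% of the variance and placed the wild-type libraries at -26.0, -22.0 and -29.8 and the ADCY3∆AT libraries at 53.2, 22.7 and 1.82. ADCY3∆AT replicate 3 thus lay nearest to wild type. The median log2 CPM of the skeletal muscle list in the same libraries was 4.39, 3.79 and 5.14 in wild type and -3.22, 1.43 and 2.76 in ADCY3∆AT. Pearson correlations of log2 CPM were from 0.980 to 0.985 within genotypes and from 0.972 to 0.985 between them.

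**Figure D2:**
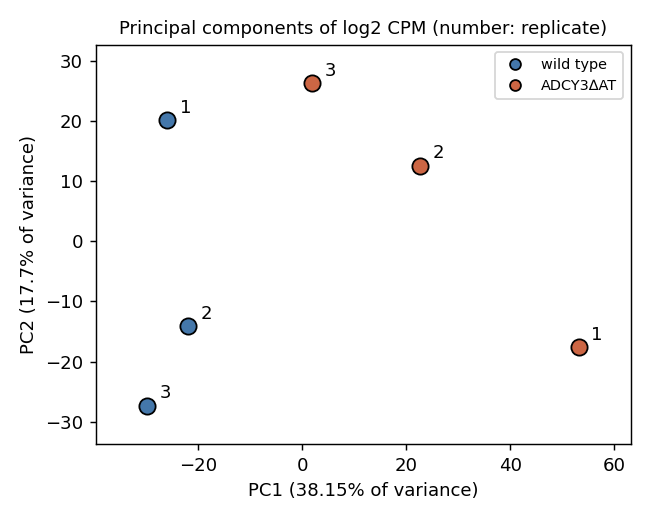
First and second principal components of log2 CPM (38.2% and 17.7% of the variance) with a point for each of the 6 libraries, coloured by genotype and numbered by replicate. On the first component the wild-type libraries lie between -29.8 and -22.0, and ADCY3∆AT replicate 3 lies at 1.82, closer to them than the other ADCY3∆AT libraries.

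Transcripts of skeletal muscle were lower in ADCY3∆AT. All 30 members of the list had a negative fold change, with a median of -3.08. None passed over all genes in edgeR, 6 were lower in DESeq2, and 29 were lower adjusted over the list alone. The list differences given next were measured in the same libraries. The lowest p-values belonged to the slow troponin Tnni1 (log2 fold change -5.57 ± 0.83, SE) and the myosins Myh7 (-5.08 ± 0.77) and Myh2 (-4.27 ± 0.82). In ADCY3∆AT, Tnni1 had a mean of 0.0416 CPM, under the mean floor of 0.0637 CPM for 3 counts. Myh7 was listed at 0 in ADCY3∆AT replicate 1, so the sizes of these falls are uncertain. Tnni1 passed in DESeq2 (adjusted p = 1.52e-09), and Myh7 (0.0599) and Myh2 (0.0647) did not. Abundant members varied widely within genotypes. Acta1, skeletal actin, had 73.8, 58.7 and 169.9 CPM in wild type and 0.94, 8.74 and 26.2 CPM in ADCY3∆AT. The list ranked lower than other genes in camera (adjusted p = 2.34e-24), and this call was lost with an estimated correlation (adjusted p = 0.672).

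The list of futile cycles that produce heat without UCP1 also ranked lower (camera adjusted p = 0.00229, and adjusted p = 0.672 with an estimated correlation). Its 16 tested members had a median log2 fold change of -0.16, and 4 were lower adjusted over the list alone, with 0 over all genes in edgeR. These included Ckmt2, a mitochondrial creatine kinase of striated muscle (-3.82 ± 0.74, SE), Ryr1, the calcium release channel of skeletal muscle (-3.02 ± 0.90), and Gk, glycerol kinase (-0.31 ± 0.08). Ckmt2 and Ryr1, both listed at 0 in ADCY3∆AT replicate 1, lay lower together with the muscle list. The median log2 CPM of that list averaged 4.44 in wild type and 0.324 in ADCY3∆AT, where replicate 1 lay lowest at -3.22. Ryr1 and Atp2a1 are members of both lists, so the calls of these lists are not independent. DESeq2 called Gk lower (adjusted p = 0.0201) and neither Ckmt2 (0.3235) nor Ryr1 (0.8005).

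Genes of fibroblasts, progenitors and extracellular matrix lay higher in ADCY3∆AT. Of 39 members 33 had a positive fold change, with a median of 0.16 on the log2 scale, and 6 were higher adjusted over the list alone, against 0 over all genes in edgeR and 5 in DESeq2. Col15a1 led, followed by the fibrillar collagens Col5a1 (log2 fold change 0.49 ± 0.08, SE) and Col5a3 (0.65 ± 0.12). Col5a3 had 30.8 ± 2.0 CPM in wild type and 48.2 ± 9.0 CPM in ADCY3∆AT (SD, n = 3 each). The list ranked higher in camera (adjusted p = 9.84e-08), which was lost with an estimated correlation (adjusted p = 0.672). Muscle transcripts moved the opposite way in the same libraries, with a median log2 fold change of -3.08.

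Endothelial markers ranked higher too (camera adjusted p = 0.00658, and adjusted p = 0.672 with an estimated correlation). Of 24 members 16 had a positive fold change, and 2 were higher adjusted over the list alone, with 0 over all genes in edgeR. These were the junction proteins Cdh5 (log2 fold change 0.28 ± 0.07, SE) and Cldn5 (0.81 ± 0.20), while Pecam1 had 0.19 ± 0.06. The list also passed in fry's test of change in either direction (adjusted p = 0.0345), and not in its test of one direction (0.484). The endothelial call was lost without ADCY3∆AT replicate 2 (adjusted p = 0.0974) or replicate 3 (adjusted p = 0.112).

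All 30 proliferation genes had a positive fold change, with a median of 0.35 on the log2 scale. No member passed in edgeR, over all genes or adjusted over the list alone, or in DESeq2, and 7 had an unadjusted p under 0.05. Cenpf had a log2 fold change of 0.63 ± 0.18 (SE), Kif11 0.45 ± 0.14 and Mki67 0.47 ± 0.17. The list ranked higher in camera (adjusted p = 1.12e-05), lost with an estimated correlation (adjusted p = 0.672). Its median log2 CPM was 1.63, 1.45 and 1.43 in wild type and 1.63, 1.87 and 2.08 in ADCY3∆AT, highest in replicate 3, in the same libraries in which the muscle list had a median log2 fold change of -3.08.

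Genes of the integrated stress and unfolded protein responses ranked higher (camera adjusted p = 0.00577, and adjusted p = 0.672 with an estimated correlation). Nupr1 was the only 1 of 32 members past the threshold adjusted over the list alone, with 0 over all genes in edgeR. Psph, an enzyme of serine synthesis, had a log2 fold change of 0.27 ± 0.09 (SE), and the transcription factor Xbp1 had -0.29 ± 0.08. This call was lost without ADCY3∆AT replicate 3 (adjusted p = 0.225).

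Markers of macrophages (28 tested, camera adjusted p = 0.00791) and B cells (10 tested, camera adjusted p = 0.0245) ranked higher, with adjusted p = 0.735 and adjusted p = 0.698 with an estimated correlation. No member of either list passed in edgeR, over all genes or adjusted over the list alone, or in DESeq2, with 5 and 3 at an unadjusted p under 0.05. Itgax had a log2 fold change of 0.97 ± 0.26 (SE), Tnf 1.02 ± 0.31 and Nos2 0.40 ± 0.15, and of the B cell genes Ighm had 1.09 ± 0.34, Jchain 0.92 ± 0.37 and Ms4a1 0.58 ± 0.23. Without ADCY3∆AT replicate 2 both calls were lost (adjusted p = 0.235 and 0.377), as they were without wild-type replicate 2 (0.215 and 0.174). The macrophage call was also lost without ADCY3∆AT replicate 3 (0.174), and the B cell call without wild-type replicate 3 (0.0611).

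Nuclear genes of oxidative phosphorylation differed by little. Of 59 members 50 had a negative fold change, but the median was only -0.04 on the log2 scale and none passed in edgeR, over all genes or adjusted over the list alone, or in DESeq2, with 1 at an unadjusted p under 0.05. Atp5g1 had a log2 fold change of -0.45 ± 0.14 (SE), Ndufb3 -0.12 ± 0.07 and Sdha -0.12 ± 0.07. The list ranked lower in camera (adjusted p = 0.00229), which was lost with an estimated correlation (adjusted p = 0.723), without wild-type replicate 2 (0.0575) and without ADCY3∆AT replicate 2 (0.153). The citric acid cycle and mitochondrial carriers behaved alike, with a median of -0.05 over 31 members, 0 past the threshold in edgeR, over all genes or adjusted over the list alone, and in DESeq2, 3 at an unadjusted p under 0.05, and a camera adjusted p = 0.00791 (adjusted p = 0.735 with an estimated correlation). Slc25a22 had -0.27 ± 0.10, Slc25a4 -0.14 ± 0.06 and Slc25a1, the citrate carrier, 0.34 ± 0.14. That call was lost without wild-type replicate 2 (0.174) or ADCY3∆AT replicate 2 (0.377).

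Amino acid and one-carbon metabolism (28 tested, median log2 fold change -0.11) and the erythroid list (9 tested, median -0.25) ranked lower, with camera adjusted p = 0.00658 and 0.00324, and adjusted p = 0.672 for both with an estimated correlation. No member passed in edgeR over all genes or adjusted over the list alone, with 3 and 1 at an unadjusted p under 0.05. Bcat1 had a log2 fold change of 1.19 ± 0.33 (SE), against the direction of its list, and passed in DESeq2 (adjusted p = 0.0346), as no other member of either list did. The log2 fold change was -0.50 ± 0.18 for Got1 and -0.21 ± 0.09 for Ivd. Of the erythroid genes Bpgm had -0.26 ± 0.09 and the globins Hbb-bt and Hbb-bs -0.29 ± 0.13 and -0.25 ± 0.13. The amino acid call was lost without ADCY3∆AT replicate 2 (0.0729) and the erythroid call without wild-type replicate 1 (0.341).

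**Figure D3:**
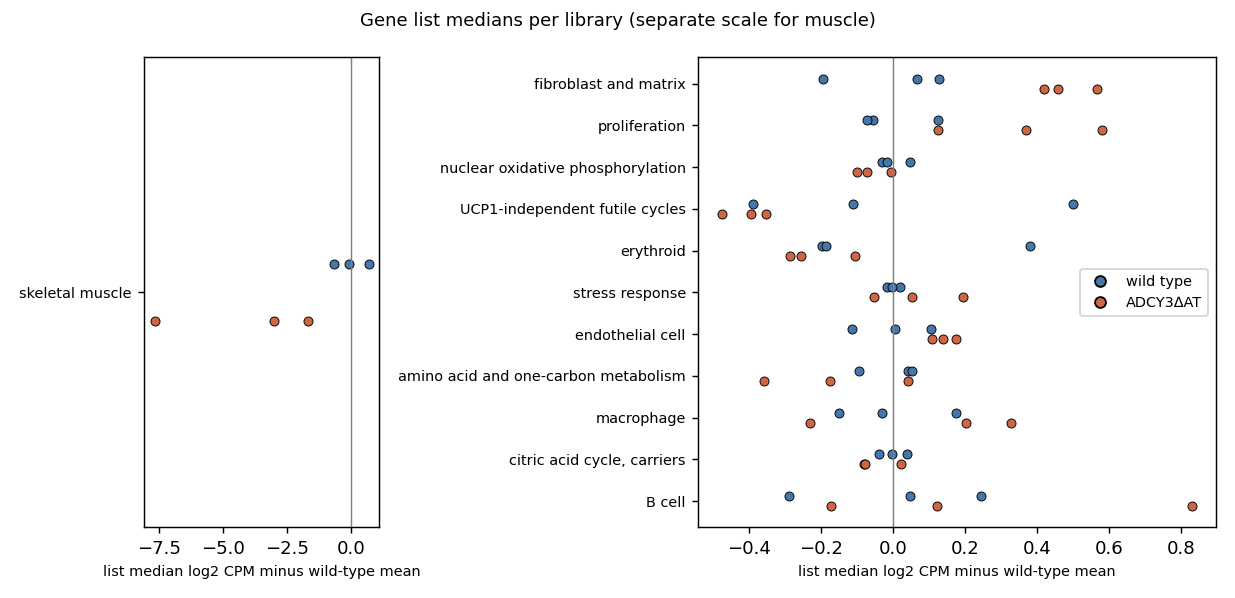
Median log2 CPM of each of the 12 gene lists past the camera threshold, as the difference from the wild-type mean (x axis, log2), with a point for each of 6 libraries coloured by genotype and a separate scale for skeletal muscle. Muscle lies 4.11 log2 units lower in ADCY3∆AT on average, with a wide spread there and replicate 1 far below the others. The fibroblast and matrix medians of all 3 ADCY3∆AT libraries lie above those of wild type.

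The thermogenic program of brown adipocytes was not called as a list (camera adjusted p = 0.0843). Of 32 members, 22 had a negative fold change, with a median of -0.05 on the log2 scale, and 0 passed over all genes in edgeR, with 9 at an unadjusted p under 0.05. DESeq2 called Ppara (adjusted p = 0.00227) higher and Gk (0.0201) and Elovl3 (0.0332) lower. Ucp1, the uncoupling protein that releases heat, had 10486 ± 160 CPM in wild type and 10092 ± 138 CPM in ADCY3∆AT (SD, n = 3 each), a log2 fold change of -0.06 ± 0.04 (SE). Ppara, a nuclear receptor of fatty acid catabolism, was higher adjusted over the list alone (0.32 ± 0.06). Dio2, which activates thyroid hormone, had -0.75 ± 0.25, with 309.7, 328.3 and 616.4 CPM in ADCY3∆AT against 623.1 to 816.2 CPM in wild type. Elovl3, a fatty acid elongase, had -0.38 ± 0.11 and Ppargc1a -0.17 ± 0.13. Cidea had -0.02 ± 0.06, a sign that turned with library totals alone, with quality weights in limma voom, and without wild-type or ADCY3∆AT replicate 1 (0.0355 and 0.0088). Without ADCY3∆AT replicate 3 the list passed as lower (camera adjusted p = 0.0272), which was lost with an estimated correlation (adjusted p = 0.799).

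Components of cyclic AMP signalling (47 tested, camera adjusted p = 0.333) included 13 genes at an unadjusted p under 0.05, 3 higher and 10 lower. Only Adcy3 was lower adjusted over the list alone. Prkar2a, a regulatory subunit of protein kinase A, had a log2 fold change of -0.23 ± 0.06 (SE) and the coactivator Crtc3 0.27 ± 0.07. The immediate targets of cyclic AMP (29 tested, camera adjusted p = 0.333) held no member past the threshold in edgeR or DESeq2. At an unadjusted p under 0.05 there were 6, of which 1 was higher and 5 were lower. Egr1 was higher (1.74 ± 0.54), and Nr4a3 (-0.99 ± 0.32) and Dio2 (-0.75 ± 0.25) were among those lower. Egr1 was low, with 0.41 to 1.99 CPM in wild type and 6.52, 2.74 and 2.47 CPM in ADCY3∆AT. In ADCY3∆AT replicate 3 Dio2 lay near wild type, at 616.4 CPM against 623.1 CPM in the lowest wild-type library. That list passed as lower without ADCY3∆AT replicate 3 (camera adjusted p = 0.0272, and adjusted p = 0.907 with an estimated correlation).

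Lipid synthesis genes were not called as a list (25 tested, camera adjusted p = 0.272, with 0 members passing in edgeR or DESeq2 and 11 at an unadjusted p under 0.05). Fasn, fatty acid synthase, had 1659 ± 221 CPM in wild type and 3682 ± 1853 CPM in ADCY3∆AT (SD, n = 3 each), a log2 fold change of 1.15 ± 0.35 (SE) with overlapping groups. Srebf1 had -0.29 ± 0.08 and Dgat1 -0.27 ± 0.08. Without ADCY3∆AT replicate 3 the list passed as higher (camera adjusted p = 0.000663, and adjusted p = 0.799 with an estimated correlation). In the lipolysis and lipid droplet list (20 tested, camera adjusted p = 0.189) Fitm1 (-3.25 ± 0.66), a lipid droplet protein of muscle, and Abhd5 (-0.24 ± 0.06), the activator of adipose triglyceride lipase, were lower adjusted over the list alone, and Hilpda had 0.55 ± 0.17. This list passed as lower without ADCY3∆AT replicate 1 (0.0335, and adjusted p = 0.348 with an estimated correlation). Fitm1 was listed at 0 in that library, so the size of its fall is uncertain.

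Among markers of adipocytes in general (20 tested, camera adjusted p = 0.121), 3 were lower adjusted over the list alone, with 0 over all genes in edgeR. They were Cfd, the adipokine adipsin (log2 fold change -0.73 ± 0.12, SE), the receptor Acvr1c (-0.36 ± 0.08) and the glucose transporter Slc2a4 (-0.24 ± 0.06). Cfd had 140 ± 8.7 CPM in wild type and 84.5 ± 15.4 CPM in ADCY3∆AT (SD, n = 3 each) and passed in DESeq2 (adjusted p = 4.47e-07). In the white adipocyte list (16 tested, camera adjusted p = 0.284) Mest was higher (0.53 ± 0.12) and Nnmt lower (-1.06 ± 0.24) adjusted over the list alone, and Igfbp3 had -0.46 ± 0.16. The adipocyte list passed as lower without ADCY3∆AT replicate 1 (0.0029, and adjusted p = 0.348 with an estimated correlation).

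The other lists were not called in camera. The adjusted p was 0.995 for cholesterol synthesis (Msmo1 and Hsd17b7, log2 fold changes -0.29 and -0.37), 0.422 for lipid and glucose uptake (Slc2a4, Pfkfb3 and Pdk1, -0.24, -0.27 and 0.29) and 0.721 for fatty acid oxidation (Acadl, Acot2 and Etfa, -0.13, 0.22 and -0.08). It was 0.995 for mitochondrially encoded messenger RNAs (mt-Nd3, mt-Cytb and mt-Nd4l, -0.46, 0.14 and 0.14), whose reads can be shared with nuclear copies. It was 0.995 for secreted brown fat factors (Nrg4, Clstn3 and Pltp, -0.30, -0.28 and 0.22), 0.113 for heat shock genes (Hspe1, Dnajb1 and Hspa1a, -0.19, 0.48 and 1.52), 0.806 for the circadian clock (Usp2, Ciart and Dbp, -0.76, -0.97 and -0.68) and 0.42 for the interferon response (Ifit3, Irf1 and Irf7, -0.44, 0.17 and -0.34). Among other cell types it was 0.272 for T and NK cells (Thy1, Il7r and Trbc2, 0.54, 0.65 and 1.04), 0.446 for neutrophils and mast cells (Kit, S100a9 and Fcer1a, 0.57, -0.64 and -1.15), 0.995 for smooth muscle and pericytes (Des, Notch3 and Smtn, -0.49, 0.36 and 0.15) and 0.132 for nerve and Schwann cells (Pmp22, Mbp and Ngfr, -0.42, -0.23 and 0.76), a list that passed in fry's test of change in either direction (adjusted p = 0.0375). Hspa1a had 36.0 CPM in ADCY3∆AT replicate 1, against 4.19 and 3.53 CPM in the other ADCY3∆AT libraries and 4.02 to 5.84 CPM in wild type, and without that library its log2 fold change was -0.39. Dnajb1 had 50.7 CPM there, against 29.8 and 28.2 CPM in the other ADCY3∆AT libraries. No member of these lists passed in edgeR over all genes or adjusted over the list alone, while DESeq2 called Nrg4 (adjusted p = 0.0128), Clstn3 (0.0430) and Des (0.0115). With an estimated correlation no list passed when any single library was left out (lowest adjusted p = 0.348). With the preset correlation, leaving out ADCY3∆AT replicate 1 brought past the camera threshold the heat shock (adjusted p = 1.68e-07) and fatty acid oxidation lists (0.0249) as lower and the T and NK cell (0.00778) and interferon lists (0.0223) as higher. The interferon list passed in the opposite direction, as lower, without ADCY3∆AT replicate 2 (8.49e-05). The clock passed as lower without wild-type replicate 1 (0.0162), mitochondrially encoded messenger RNAs as higher without wild-type replicate 2 (0.0125) and heat shock genes as lower without wild-type replicate 3 (0.0433). Epithelial genes (Lrrn4, Krt10 and Msln, -0.82, 0.10 and 0.03) and sex-linked genes (Ddx3y, Uty and Eif2s3y, -0.24, -0.06 and 0.11) had too few tested members for a list test, and the signs turned for Krt10 without ADCY3∆AT replicate 1 (-0.01), for Msln without wild-type (-0.0046) or ADCY3∆AT replicate 3 (-0.015) and for Eif2s3y without wild-type replicate 2 (-0.09) or ADCY3∆AT replicate 1 (-0.18). For the mitochondrial and secreted factor lists camera pointed higher while the median fold changes were -0.03 and -0.03, for cholesterol synthesis camera pointed lower while the median was 0.02, and for heat shock genes the median was -0.12 and the mean 0.07.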

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

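The added row passed under each of the 17 alternatives in which it was tested, with adjusted p-values from 3.54e-43 (DESeq2) to 0.00119 (edgeR robust). None of them bears on whether the same reference index served both genotypes, on which this call depends. The count of genes, 1 in the edgeR fit, was 229 with DESeq2 (88 higher, 141 lower), 2 with limma voom with or without quality weights, 2 with edgeR robust, 2 with one surrogate variable and 214 with no low-count filter (59 higher, 155 lower). Leaving out single libraries gave 1 to 66, with 66 without ADCY3∆AT replicate 3. With no filter, 30714 genes were tested and the estimated prior degrees of freedom were 12 against 4.27. The cause was not tested. RLE factors, library totals only, the stricter filter, removal of mitochondrially encoded genes and an adjusted p of 0.1 left the count at 1.

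Same-numbered libraries deviated from their group means with correlations of -0.09, -0.13 and -0.09, which shows no strong shared deviation. With 3 libraries per group this cannot exclude that the numbers mark pairs. The replicate block gave 3 genes and 12 lists.

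Adcy3 kept its direction throughout. It passed with DESeq2 (log2 fold change -0.78, adjusted p = 4.26e-07) and with no low-count filter (-0.78, adjusted p = 0.00321), and without single libraries it ranged from -0.99 to -0.68. The range of its adjusted p over the alternatives was 4.26e-07 to 0.589.

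Camera with the preset correlation called 12 of the 31 lists tested. Over the same lists, 0 were called with estimated correlation and 0 with fry in one direction. Even skeletal muscle, with all 30 members lower, had an unadjusted camera p of 0.0769 with estimated correlation. The lack of calls there thus does not show that no list differs. Without single libraries the preset correlation called 7 to 18 lists (7 without ADCY3∆AT replicate 2), which can include lists outside the 12. Fry's test of change in either direction called 2 of 31 lists, endothelial cell (adjusted p = 0.0345) and nerve and Schwann cell (0.0375). With estimated correlation, 0 were called without any single library, an alternative chosen after seeing the data. The cause was not tested. The first principal component held 28.2% to 46.6% of the variance under other filters and scaling, chosen after seeing the data. DESeq2 without single libraries, also chosen then, called 73 (without ADCY3∆AT replicate 2) to 654 (without ADCY3∆AT replicate 3).

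Of 1822 comparisons for 108 genes selected by the rule, 1746 kept side and direction, 66 newly passed and 10 changed sign, none of them past the threshold in either fit. Cidea was at 0.000448 with library totals only, 0.000759 with limma voom with quality weights and -0.0498 to 0.0355 without single libraries, where Hspa1a ranged from -0.39 to 1.99, Krt10 from -0.0106 to 0.22, Msln from -0.0150 to 0.0665 and Eif2s3y from -0.18 to 0.30. The 12 lists called kept side and direction in 104 of 143 comparisons and lost the call in 39. The 19 lists not called did so in 185 of 227, newly passed in 12 and changed direction in 30. For cholesterol synthesis the adjusted p was then 0.996 (fry), 0.801 (camera on ranks), 0.866 (replicate block), 0.99 (stricter low-count filter) and 0.982 (library totals only), and 0.268 to 0.956 without single libraries. For mitochondrially encoded messenger RNAs it was 0.996 (fry), 0.957 (camera on ranks), 0.95 (replicate block) and 0.0125 to 0.999, for secreted brown fat factors 0.993 (fry), 0.944 (camera on ranks), 0.993 (library totals only) and 0.691 to 0.955, and for smooth muscle and pericyte 0.996 (fry), 0.993 (library totals only) and 0.289 to 0.964. Neutrophil and mast cell gave 0.875 (stricter low-count filter) and 0.258 to 0.928. Without single libraries the range was 0.0272 to 0.955 for cAMP-responsive immediate targets, 0.0249 to 0.955 for fatty acid oxidation, 0.0162 to 0.955 for circadian clock and 8.49e-05 to 0.869 for interferon response, which passed as higher without ADCY3∆AT replicate 1 (0.0223) and as lower without ADCY3∆AT replicate 2 (8.49e-05). The cause was not tested.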

Other observations

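The tests on muscle transcripts, on ADCY3∆AT replicate 3, on Trpc2 and Xntrpc and on the genes beside Adcy3 were chosen after the patterns had been seen, and only the counts over splits of the samples were planned before their results.

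Skeletal muscle transcripts were lower in ADCY3∆AT. Within genotypes the first component of the list held 97.2% of its variance, but a muscle program regulated together would also give this, so it does not separate muscle tissue carried along with the dissected fat from an effect of genotype. The median of the list ranged over 5.98 log2 units among ADCY3∆AT libraries, against a difference of 4.11 between genotypes. Without the most distant library, replicate 1 at -3.22, the range was 1.34, against 1.35 among wild-type libraries, so both explanations stay open. The difference of 4.11 includes replicate 1 and is smaller without it. The other ADCY3∆AT libraries lay at 1.43 and 2.76, against 3.79 to 5.14 in wild type. Of 131 genes lower in DESeq2, outside the list and among the genes kept by the low-count filter, 8.4% followed the muscle list within genotypes (correlation above 0.9), against 2.41% of all tested genes (one-sided Fisher exact p = 0.000328). The ADCY3∆AT libraries lay in the same order on the first principal component, at 53.2, 22.7 and 1.82, with replicate 3 nearest to wild type. A gene that fell least in replicate 3 could thus follow the list without a link to muscle. The Fisher test also treats genes measured in the same libraries as independent. Whether what lowered the muscle list accounts for part of those falls is therefore not decided by these data.

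ADCY3∆AT replicate 3 lay near wild type on the first principal component, and of the 200 lowest p-values in a fit without it, 29.5% had it closer to the other ADCY3∆AT libraries, against 67% to 89.5% when each other library was held out, which is what a wrong label would give. The summed CPM of the Adcy3 row and the added row was taken up only after that share had been seen. It argues against a wild-type library carrying the wrong label, since it was 506 in this library, all of it in the Adcy3 row. In wild type the sum was 1129 to 1305, so this library lay 6.55 wild-type SDs under the lowest. If the added row were missing from the index used for this library its reads could be lost, but the Adcy3 row alone, which would then lose none, was also 3.78 wild-type SDs under the lowest wild-type library (505.6 against 651.9 CPM). Why this library resembles wild type otherwise was not tested.

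Trpc2 (chromosome 7, 102083116 to 102096396) was listed at 0 in all 3 wild-type libraries and had 0.722, 0.549 and 0.452 CPM in ADCY3∆AT, and it was called by limma voom, with or without quality weights, and by DESeq2 (adjusted p = 3.57e-05), but not by edgeR (adjusted p = 0.141). The overlapping gene Xntrpc (102065713 to 102096864) went the other way, with 1.26, 1.36 and 0.962 CPM in wild type and 0.0656, 0.142 and 0.581 CPM in ADCY3∆AT. The summed CPM of both rows was 1.43-fold higher in wild type and its ranges overlapped, which is consistent with reads shared between overlapping genes. Both changes are uncertain for that reason, and a change of transcript use in ADCY3∆AT stays open as untested.

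A further hypothesis was that genes beside the edited locus respond with it. Of 26 tested genes within 1 Mb of Adcy3, 5 (19.2%) had an unadjusted p under 0.05, against 11% of other genes (two-sided Fisher exact p = 0.199). The difference did not pass, and 26 genes are too few to exclude it. Those with low p-values were Fam228a, Ubxn2a, Ncoa1, Dnajc27 and Cenpo, with log2 fold changes of -0.72, -0.22, -0.21, -0.25 and 0.29.

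The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 1 gene in edgeR and the highest other 4, and 3 of the 10 splits, counting the real split, gave at least as many as the real split. For gene lists in camera the real split gave 12 and the highest other 20, and 5 of the 10 splits, counting the real split, gave at least as many as the real split. In DESeq2 the real split gave 229 genes and the highest other 137, the split that joins ADCY3∆AT replicate 3 to wild-type replicates 1 and 2, and 1 split, the real one, gave as many.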
